A study of Caenorhabditis elegans with 2 samples.

How the data were processed

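The samples were 2 biological replicates of ChIP-seq with an anti-GFP antibody on whole young adult hermaphrodites of strain OP465, which expresses NHR-179 with a C-terminal GFP-FLAG tag. The labels number them 2 and 3 and state that chromatin was fragmented by sonication. Both belong to 1 group.

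The authors deposited 8 peak lists, 4 on each of the builds ce10 and ce11: 1 list per replicate, a list from the pooled replicates, and an optimal list made from these by the irreproducible discovery rate, a measure of how well ranked peaks recur. Per the deposited file descriptions, the replicate and pooled lists were called on aligned reads together with a control alignment and hold background regions as well as peaks. The aligner, peak caller, versions, read filters and threshold were not given in the sources used here. Alignments, signal tracks and the control were not analysed here. Each peak has a deposited signal value, whose scaling is not stated, and a deposited −log10 of a q value (q-value), which ran from 1.66 to 2.48 in the optimal ce11 list. The signal is the authors' score and was used only to rank, select or describe peaks, and replicates were compared by its ranks. The files hold no counts, so depth is unknown and no interval that needs depth is given.

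The optimal list equals the 256 highest peaks of the pooled list by signal on ce11, and the 208 highest on ce10. On ce11 the pooled list held 9606 peaks, replicate 2 held 12866 and replicate 3 held 13745. Chromosome lengths and genes came from the WBcel235 assembly, the same as ce11, with Ensembl release 115 gene models. The RefSeq annotation of that assembly gave symbols where Ensembl had none, mitochondrial gene names and tRNA products. No coordinate was converted between builds.

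Peaks were represented by their summits. Shares of summits near transcript starts, in gene features, near tRNA, snRNA, snoRNA and rRNA genes, and in the middle 50% of autosomes were compared with 10000 uniform placements within the same chromosomes, 2-sided, with 1 added to the count of draws in each p. Each summit was put in the first fitting class of coding exon, untranslated exon, non-coding RNA gene, intron and intergenic, and pseudogenes counted as intergenic unless another class covered them. Peaks per chromosome were compared with 10000 draws by length over the 6 nuclear chromosomes. Gene lists were compared by Fisher's exact test among 19973 nuclear protein-coding genes, for the nearest transcript start within 1000 bp of a summit. Motifs and words of 6 bases within 50 bp of summits were compared by Fisher's exact test with windows centred 500 bp to either side, leaving out those within 150 bp of another summit. Words were found on I to III and tested again on IV, V and X. The Benjamini-Hochberg adjustment ran over the 6 chromosomes, the 5 classes, 28 lists, 14 motifs or 2080 words, with a threshold of 0.05. Replicates were compared on their top 256 peaks, with summits within 100 bp called shared. The loci of nhr-179 and unc-119 were taken with 20 kb on either side.

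The named genes were those of the 25 optimal peaks with the highest signal, up to 4 targets of each list past the threshold and of the nuclear hormone receptors, nhr-179 and unc-119, and the 4 words with the lowest p on I to III. A peak was named by the nearest protein-coding start within 1000 bp, otherwise by the gene it lay in, otherwise by the nearest start. These choices, lists, motifs and tests were fixed before the data were examined. Alternatives used the top peaks of either replicate alone, the upper 50% of the optimal list by signal, the top 512 pooled peaks, other distances, backgrounds, windows and gene assignments, and ce10. Alternatives with nuclear summits only, autosomal summits only, no summits near small RNA genes or none in non-coding RNA genes (with and without mitochondrial peaks), and the sequence GCGCAGGG, were added after the data were seen.

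The tests were tried on simulated summits. With an effect planted in 20 sets, the chromosome, promoter, small RNA, central share, gene list and motif tests each made the planted call in 20 of 20 sets. With nothing planted they made a call in 0, 1, 0, 2, 1 and 1 of 20. The planted effects were large. In the same order they were 35% of peaks on X, 60 summits added near starts, 15 near small RNA genes and 80 in chromosome centres. The 80 were drawn over all nuclear chromosomes and those on X were then left out, so fewer were tested. For the gene list and motif tests, 10 collagen genes and a nuclear receptor site in 40 windows were planted. Smaller effects were not tried, so these runs do not show that smaller differences would be found. A word planted in 20 of 79 windows was found in 10 of 10 sets, and 0 of 10 sets gave a call without it. The summits without a planted effect were placed uniformly, whereas real summit windows had 45.6% GC and their flanks 35.3%. The rates of false calls of the motif and word tests therefore do not cover that difference. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.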

Results

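Whole young adult hermaphrodites of Caenorhabditis elegans carrying a tagged copy of NHR-179, a nuclear hormone receptor, were assayed by ChIP-seq with an antibody against GFP. Strain OP465 carries a transgene for NHR-179 with GFP and FLAG at its C-terminus in an unc-119 mutant background. Animals were collected 64 hours after synchronization as starved L1 larvae. The 2 biological replicates, numbered 2 and 3 in the labels, formed 1 group, so peaks could be compared between replicates and with the genome, and not between treatments. The files held peak positions and scores without read counts, so the depth of each sample is unknown. Coordinates are on ce11, counted from 1. Intervals on shares are exact Clopper-Pearson 95% intervals over peaks or genes and cover counting error only, and n in the tests counts peaks, which are not independent replicates.

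The peaks with the highest signal lay on the mitochondrial genome. The authors' optimal list, which combined both replicates, held 256 peaks, of which 233 were nuclear and 23 mitochondrial. The 23 mitochondrial summits shared 4 intervals that covered 12802 bp, or 92.8% of the mitochondrial genome, and their signal, the authors' value for each peak, ran from 497.7 to 7171. The highest summit stood at position 4701 in the coding exon of CYTB, the cytochrome b gene, with a signal of 7171, in the interval from 544 to 6685, which also held the summit of COX3 (signal 5638). ND5 (interval from 10597 to 13030, signal 5270) and ND4 (interval from 6753 to 10619, signal 4609) followed, and all of these genes encode subunits of the respiratory chain. Other mitochondrial summits were named by COX1, COX2, ND1, ND2, ND3, ND4L, ND6 and ATP6. Nuclear peaks had a median signal of 94.7 and a maximum of 328.9. Optimal peaks were 132 to 6142 bp wide, with a median of 444 bp.

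Because 23 of the 25 highest peaks were mitochondrial, the 25 highest nuclear peaks were also named, a choice made after the values were seen. The highest nuclear peak, on V from 12303511 to 12303796 with a signal of 328.9, lay inside frm-7 with its summit in the snoRNA gene C51F7.4. The next, on V from 8500446 to 8500686 with a signal of 305.9, lay in an intron of pxn-1 beside the snoRNA gene ZK994.7. The peaks named by sre-23, str-56, Y23H5B.5, wrt-3, cutl-18 and W03C9.1 also lay within 200 bp of a snoRNA gene, which made 8 of the 25. A further 5 lay within 200 bp of a tRNA gene, those named by him-4, xol-1, C04A11.5, sulp-3 and M02F4.2. The him-4 peak (X from 9743455 to 9743898, signal 189.4) had its summit between a pair of tRNA-Ala genes. The peak named by xol-1, a switch gene of sex determination, had its summit at -4648 bp from the gene's start, beside a tRNA-Arg gene (X from 8036443 to 8036886, signal 175.9). The sulp-3 peak (signal 146.9) had no summit within 100 bp in the list of replicate 3.

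The other 12 of the 25 lay near no small RNA gene of the classes tested. The highest was an intergenic peak on III from 931517 to 931670 with a signal of 194.0, whose nearest start was that of fbxa-55 at 4475 bp. On I, a peak from 13463881 to 13464067 (signal 172.4) had its summit in rpr-1, the RNA component of RNase P, within ints-8. The peak named by nas-30 on I had a signal of 151.5. The remaining peaks of this set lay on X and were named by mom-1, ZK899.6, nspc-17, W02H3.3, K02D3.1, F55G7.5, gtr-1, F22H10.2 and ins-39, with signals from 141.0 to 179.7. Those named by mom-1, nspc-17, W02H3.3, gtr-1 and ins-39 held the sequence GCGCAGGG within 50 bp of the summit. In all, 14 of the 25 were on X, and 5, those of sre-23, ints-8, nspc-17, wrt-3 and ins-39, had a summit within 1000 bp of a protein-coding transcript start.

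Most nuclear summits lay near small RNA genes. Of the 233 nuclear summits, 103 lay within 200 bp of a tRNA gene (44.2%, 37.7 to 50.8%), 42 within 200 bp of a snoRNA gene (18.03%, 13.3 to 23.6%) and 11 within 200 bp of an snRNA gene (4.72%, 2.38 to 8.29%). Uniform placement gave 0.414%, 0.155% and 0.0438%. No nuclear summit lay near an rRNA gene, and the interval allows a share of up to 1.57%. For the 4 classes together, 155 nuclear summits, 66.5% (60.1 to 72.6%), were near such a gene against 0.613% by placement. With the mitochondrial peaks, as the test was fixed, the share was 166 of 256, 64.8% (58.7 to 70.7%) against 4.65%, a ratio of 13.96 (2-sided placement test, n = 256, p = 0.0002, the smallest that 10000 placements can give). In the pooled list, which also holds background regions, 404 of the 9350 nuclear summits outside optimal peaks (4.32%, 3.92 to 4.75%) were near these genes, a lower share than in the optimal peaks (2-sided Fisher's exact test, p = 5.8e-140, added after the data were seen).

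**Figure D1:**
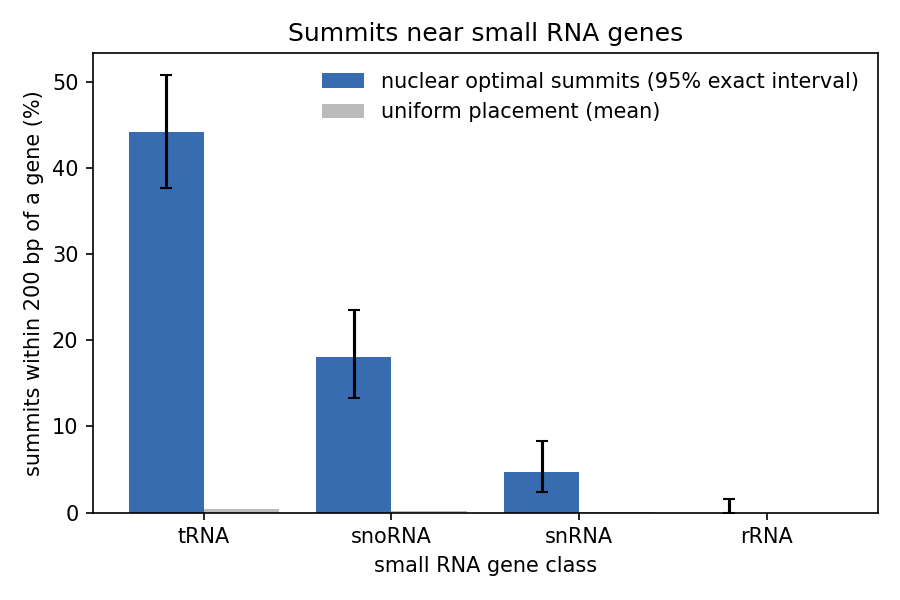
Share of the 233 nuclear optimal summits within 200 bp of a gene of each small RNA class (percent, blue bars with exact 95% intervals) beside the mean share under uniform placement (grey bars). The tRNA bar stands at 44.2% and the snoRNA bar at 18.03%, against placed shares of 0.414% and 0.155%.

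Among the genes themselves, 116 of 612 nuclear tRNA genes (18.95%, 15.9 to 22.3%), 41 of 346 snoRNA genes (11.8%, 8.64 to 15.7%) and 9 of 129 snRNA genes (6.98%, 3.24 to 12.8%) had an optimal summit within 200 bp. The tRNA genes near a summit had a mean of 12.4 identical copies in the genome and the others 10.6. The snRNA genes included 4 that encode the spliced leader SL2, namely sls-2.1, sls-2.2, sls-2.4 and sls-2.9, named after their values were seen. Of these, sls-2.1 on II from 5844865 to 5844974 lay by the summit with the highest signal, 133.1.

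Chromosome X carried 106 of the 233 nuclear peaks, 45.5% (39.0 to 52.1%), against 17.7% by length, a ratio of 2.57 (2-sided placement test, n = 233, adjusted p = 0.0008). The shares of all chromosomes add up to 100%, so those of the autosomes fall as that of X rises, and the 127 autosomal peaks were also compared with the lengths of the 5 autosomes alone, a test added after the data were seen. I, II, III, IV and V held 20, 28, 31, 20 and 28 of them (15.7%, 22.05%, 24.4%, 15.7% and 22.05% against 18.3%, 18.5%, 16.7%, 21.2% and 25.3%), and none passed (n = 127, adjusted p from 0.176 to 0.553). The pooled list outside optimal peaks had 27.1% of its nuclear summits on X, and against it the ratio for X was 1.68 (n = 233, adjusted p = 0.0012). Over the alternatives the adjusted p for X ran from 0.0006 to 0.0012. Without the summits near small RNA genes III held 24.4% of 78 peaks, above its length (n = 78, adjusted p = 0.0354). Among autosomal summits, 67 of 127 (52.8%, 43.7 to 61.7%) lay in the middle 50% of their chromosome against 49.9% by placement (n = 127, p = 0.591). In the top peaks of replicate 2 alone the share was 58.7% (n = 143, p = 0.048).

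**Figure D2:**
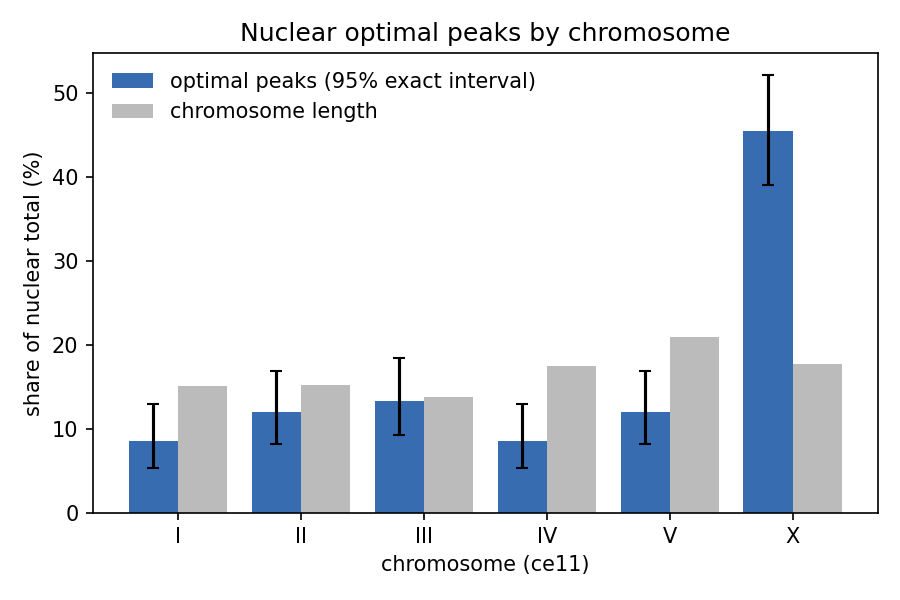
Share of the 233 nuclear optimal peaks on each ce11 chromosome (percent, blue bars with exact 95% intervals) beside the share of that chromosome in nuclear length (grey bars). X holds 45.5% of the peaks and 17.7% of the length.

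Summits did not gather at the starts of protein-coding genes, and 93 of the 256 lay in non-coding RNA genes. Of the 256 summits, 118 (46.1%, 39.9 to 52.4%) lay within 1000 bp of a protein-coding transcript start, against 43.6% placed (n = 256, p = 0.43). Non-coding RNA genes held 36.3% (30.4 to 42.5%) against 3.5% placed (n = 256, adjusted p = 0.000333). The classes exclude each other, so this excess lowers the shares of the rest, which were 15.6% for coding exons, 15.2% for introns, 2.73% for untranslated exons and 30.1% for intergenic sequence, against 27.8%, 29.0%, 4.61% and 35.1%. Of the 233 nuclear summits, coding exons held 21 (9.01% against 23.1%) and introns 39 (16.7% against 31.9%). Among the 144 nuclear summits outside non-coding RNA genes, compared with placements outside them in a test added after the data were seen, intergenic sequence held 77 (53.5% against 38.3%) and coding exons 21 (14.6% against 23.9%), both past the threshold (n = 144, adjusted p = 0.0032 and 0.0236). Introns held 39 (27.1% against 32.7%) and untranslated exons 7 (4.86% against 5.08%), which did not pass (n = 144, adjusted p = 0.219 and 1). With the mitochondrial summits, intergenic sequence held 47.2% against 34.4% and coding exons 24.5% against 32.04% (n = 163, adjusted p = 0.0024 and 0.0436). Summits outside non-coding RNA genes can still lie within 200 bp of a small RNA gene. Of the 78 summits away from small RNA genes, intergenic sequence held 48.7% against 37.0%, which did not pass (n = 78, adjusted p = 0.068). Introns held 11.5% of these 78 against 32.95% and coding exons 19.2% against 23.4% (n = 78, adjusted p = 0.0005 and 0.577). With transcript starts of all gene types, 88.3% of summits lay within 1000 bp of a start against 57.0% placed (n = 256, p = 0.0002), and in the top 512 peaks of the pooled list the protein-coding share was 48.6% against 41.9% (n = 512, p = 0.0018).

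None of the 28 gene lists passed the threshold among the 94 protein-coding genes that were the nearest within 1000 bp of a nuclear summit. These genes are called targets by position only, as no untagged strain or other factor was analysed here and it is not known which peaks reflect binding of NHR-179. Nuclear hormone receptors, the family of NHR-179, had 1 target among 274 genes, nhr-255, where 1.29 were expected (2-sided Fisher's exact test, adjusted p = 1). Its peak lay on X from 15741798 to 15742241 with the summit at -590 bp from the start and a signal of 83.4, also within 200 bp of a tRNA-Leu gene. By Fisher's exact test 3 lists had an unadjusted p under 0.05, and their adjusted p was 0.366. These were collagens, proteins of the cuticle, with col-85, col-138 and col-184 (3 of 166 genes), proteases with nas-4 and nas-10 (2 of 63) and vitellogenins, the yolk proteins, with vit-2 (1 of 6), all named after their values were seen. Ribosomal proteins had rpl-3 and rpl-15 among 78 genes, and chemoreceptors had sre-23 and srv-16 among 1171 genes where 5.51 were expected (Fisher's exact test, adjusted p = 0.366 and 0.619), also named after their values were seen. Other transcription factors, UDP-glycosyltransferases, lipid metabolism, histones, sperm proteins, muscle, intestine and neuron markers had 0 targets each, in lists of 161, 67, 82, 72, 54, 30, 12 and 15 genes. In that order 0.758, 0.315, 0.386, 0.339, 0.254, 0.141, 0.0565 and 0.0706 targets were expected. A count of 0 therefore says little about these lists. Of the 95 nuclear peaks with a target, 59 also lay within 200 bp of a small RNA gene. In the top peaks of replicate 2 alone, collagens passed with 5 genes (Fisher's exact test, adjusted p = 0.0399), and with all genes within 1000 bp counted, ribosomal proteins passed with 4 genes (Fisher's exact test, adjusted p = 0.031).

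The core site of nuclear receptors, RGGTCA, was within 50 bp of 12 of 256 summits (4.69%, 2.45 to 8.04%) and in 3.56% of 505 flank windows (Fisher's exact test, adjusted p = 0.988). Its variant AGTTCA was in 8.20% of summit and 7.72% of flank windows (Fisher's exact test, adjusted p = 1). The repeat GAGAGA was more frequent at summits, 12.5% against 5.54%, and TTTTTTTT less frequent, 3.12% against 11.3% (Fisher's exact test, adjusted p = 0.0106 and 0.00126). The other 12 of the 14 motifs did not pass. Summit windows had 45.6% GC and flanks 35.3%, and against genome windows of matched GC, of which 8.61% held GAGAGA and 3.7% TTTTTTTT, neither call held (Fisher's exact test, adjusted p = 0.48 and 1). Both calls also ended in the upper 50% of peaks by signal, with similar shares (GAGAGA 13.3% against 4.82%, TTTTTTTT 3.12% against 10.8%, Fisher's exact test, adjusted p = 0.066 each). Away from small RNA genes GAGAGA was in 16.7% against 9.62% and TTTTTTTT in 1.28% against 12.2% (Fisher's exact test, adjusted p = 0.382 and 0.0687). With windows of 25 bp neither passed (GAGAGA 7.03% against 3.56%, TTTTTTTT 1.56% against 4.75%, Fisher's exact test, adjusted p = 0.318 each). GAGAGA did not pass on the autosomes (12.6% against 7.48%) nor TTTTTTTT without replicate 2 (3.91% against 7.57%). Both passed with windows of 100 bp (26.6% against 9.90% and 12.5% against 22.2%) and against the lower 50% of the pooled list (12.5% against 6.62% and 3.12% against 9.46%).

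On chromosomes I to III, 6 of 2080 words of 6 bases differed between 79 summit windows and 158 flanks, and 2 of the 6 passed again on IV, V and X, adjusted over the 6. The 4 with the lowest p were AGCGTG (13.9% of summits, 0.633% of flanks), TTAAAA (7.59%, 29.7%), AAAAAT (17.7%, 43.7%) and ACCCGC (12.7%, 0.633%), each with an adjusted p of 0.0469. On IV, V and X, AAAAAT was in 18.2% of summit and 45.5% of flank windows (Fisher's exact test, p = 1.03e-06 adjusted over all words). There AGCGTG was in 6.49% and 2.27%, TTAAAA in 14.3% and 22.7%, and ACCCGC in 3.25% and 0.649%. These 3 did not pass (Fisher's exact test, p = 0.186, 0.194 and 0.21 adjusted over all words). Summit windows had more GC than flanks, which by itself can make words of A and T, such as AAAAAT and TTAAAA, rarer at summits. Which of the named words pass against windows of matched GC is not given here. The count of 6 was 0 without replicate 2 and 2 without replicate 3, 0 in the upper 50% of peaks by signal and away from small RNA genes, 12 against windows of matched GC and 84 in the top 512 pooled peaks. On IV, V and X, with more windows, 190 words passed, and in the same order 116, 123, 67, 7, 80 and 375. On IV and V without X, with 48 windows, 2 words passed and 0 of the 6 passed again, so the repeat was not seen without X.

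The replicates had 121 of their top 256 peaks in common (47.3%, 41.0 to 53.6%), with summits within 100 bp, against 2.93% by placement (n = 256, p = 0.0002). Among nuclear peaks 101 of 234 in replicate 2 (43.2%, 36.7 to 49.8%) had a partner in replicate 3. In the top 1280 peaks the share was 24.0% against 0.859% placed. Of the optimal peaks, 229 of 256 (89.5%, 85.0 to 92.9%) had a summit within 100 bp in both full replicate lists, and 46.5% (40.3 to 52.8%) in the top 256 of both, or 37.5% with summits within 50 bp and 53.1% with an overlap of 1 bp. The share was 82.8% of the upper 50% by signal and 23.2% of the top 512 pooled peaks, lists shorter and longer than the 256 they were compared with, which by itself raises and lowers it. For 17 optimal peaks neither replicate's top 256 held such a summit. Across the 2350 of 9583 nuclear pooled peaks found in both replicates, the signals had a Spearman rho of 0.361. Across the 209 nuclear optimal peaks found in both, rho was 0.249. These were selected by their pooled signal, to which both replicates contribute, and such a selection can itself lower rho. Its effect was not measured and cannot be told apart from weak agreement of the replicates. Across 20 mitochondrial peaks rho was 0.878, and all of these values are across peaks and not across samples.

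**Figure D3:**
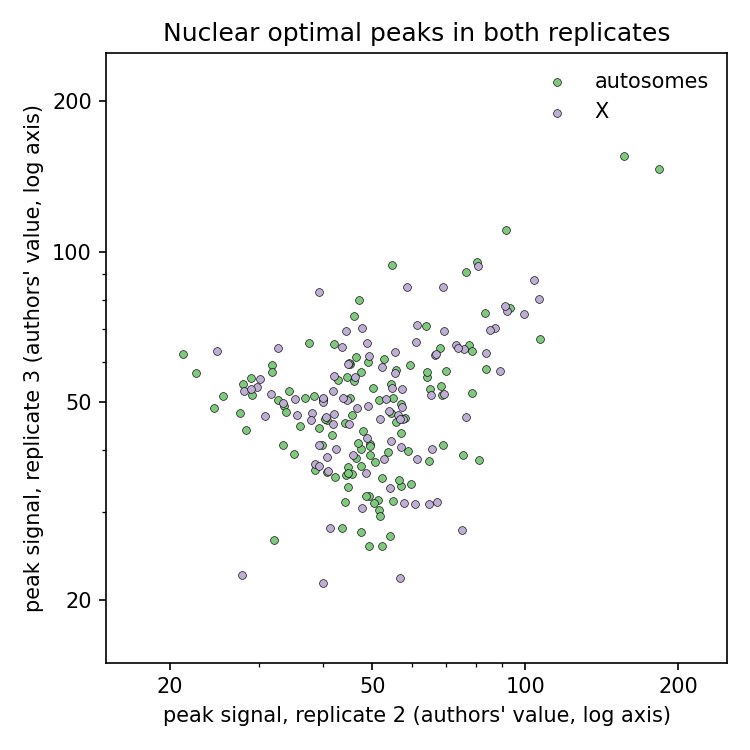
Signal of each nuclear optimal peak in replicate 2 (horizontal) and replicate 3 (vertical), as the authors' values on log axes, for the 209 peaks with a summit within 100 bp in both lists, with autosomal peaks in green and X peaks in purple. The Spearman rho is 0.249. The selection of these peaks on the pooled signal can lower rho, by an amount that was not measured.

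At the loci of the transgene, no list held a summit near nhr-179. The window around nhr-179 (WBGene00017512), its gene and 20 kb on either side on V from 1595723 to 1638860, had 0 summits in the optimal, pooled and both replicate lists, where the rate elsewhere on V gave 0.0578, 4.18, 5.6 and 6.19. Of the 32-base words of this window, 6.93% occur elsewhere in the genome. The window around unc-119 (WBGene00006843), the marker gene of the strain, on III from 10882641 to 10928935, had 0 optimal, 3 pooled, 1 replicate 2 and 4 replicate 3 summits, where 0.104, 3.78, 5.6 and 5.43 were expected.

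On ce10 the authors' optimal list held 208 peaks, against 256 on ce11. The mitochondrial count was 23 on both builds, and X held 87 of 185 nuclear peaks (47.0%) on ce10. The nuclear signal ran from 81.5 to 328.9 on ce10 and from 74.7 to 328.9 on ce11.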

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

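The alternatives with nuclear, autosomal or X summits only, without summits near small RNA genes, outside non-coding RNA genes, and with the pooled list at the transgene loci were chosen after the data were seen. Of 254 alternative values for 28 results, 177 kept their direction and side of the threshold (the core site on the autosomes equalled its flanks) or, with no test, moved by no more than their interval or 1.5 times a count, 19 lost the threshold, 5 gained it, 24 reversed and 29 others moved. Each result that reversed was one that did not pass before. The X share (38.0 to 49.5%), small RNA proximity (49.6 to 67.6%) and replicate agreement (24.0 to 56.0%) stayed past the threshold in each alternative run. The cause of the changes below was not tested. Without summits near small RNA genes, III held 24.4% of peaks, above its length and not below and past the threshold, coding exons held 19.2% of summits, not past the threshold, and 0 motifs and 0 words on I to III passed (7 on IV, V and X). Outside non-coding RNA genes, intergenic sequence held 47.2% of summits (53.5% of nuclear ones), above placement and not below and past the threshold, and introns 23.9% (27.1%), not past the threshold. The other reversals were not past it. Intergenic sequence rose above placement in the upper 50% by signal (33.6%), away from small RNA genes (48.7%) and against the pooled list (33.0% of nuclear summits). Untranslated exons did so in the top 512 pooled peaks (5.27%) and away from small RNA genes (6.41%). The central share fell below placement away from small RNA genes (45.7%) and against transcript starts (52.8%). The promoter share of nuclear summits (40.8%) fell below the 46.2% expected from the pooled list. III lay above its expectation in the top 512 pooled peaks (13.9%), against transcript starts or the pooled list (13.3%), and among autosomal peaks (24.4%), as did II there (22.05%), and III held 12.02 to 14.1% with each replicate left out, above its length only without replicate 3. The core site RGGTCA fell below its controls with 25 bp windows (1.56%) and matched GC (4.69%), and AGTTCA in the upper 50% by signal (7.03%), the top 512 pooled peaks (6.45%), away from small RNA genes (6.41%) and with 25 bp windows (3.12%). Nuclear hormone receptors had 4 targets in the top 512 pooled peaks, above the 3.02 expected. With each replicate left out, the central share was 56.5 to 58.7%, past the threshold only without replicate 3, gene lists past it numbered 0 to 1, motifs 1 to 3, words on I to III 0 to 2, and unc-119 summits 1 to 4 (pooled list 3). With the top 512 pooled peaks the promoter share was 48.6% and passed, 84 words on I to III passed, and 84.4% of peaks were in both replicates. The promoter share passed with starts of all gene types (88.3%), untranslated exons passed against the pooled list (3.00% of nuclear summits), and 1 gene list passed with all genes within 1000 bp. Counting words on I to III, 0 motifs and 0 words passed in the upper 50% by signal, on the autosomes 1 motif, with 25 bp windows 0 motifs and 1 word, with 100 bp windows 33 words, and against GC-matched windows 0 motifs and 12 words. Optimal peaks in both replicates were 65.6% within 50 bp, 98.0% within 200 bp, 99.6% by 1 bp overlap and 97.3% by 50% reciprocal overlap, and those in the top 256 of both 23.2 to 82.8% over the alternatives. The top 256 pooled peaks equal the optimal list, so that comparison tests nothing, and depth is unknown, so its effect could not be judged.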

Other observations

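The tests below, other than placement near protein-coding starts, were chosen after the patterns they address were seen, and those of an X bias of the whole peak calling, for all peaks and for those outside both sets, and of single-copy genes after related tests had been read. On X, 80 of 276 tRNA genes (29.0%, 23.7 to 34.7%) had an optimal summit within 200 bp, against 36 of 336 on the autosomes (10.7%, 7.62 to 14.5%), an odds ratio of 3.4 (2-sided Fisher's exact test, p = 1.32e-08). Among tRNA products, tRNA-Ala genes had the highest share, 13 of 34 (38.2%, 22.2 to 56.4%), which did not pass adjustment over the products (Fisher's exact test, adjusted p = 0.134). Of the 78 nuclear summits away from small RNA genes, 11 lay in other non-coding RNA genes, among them rpr-1, srpr-2.2 on III (signal 115.9), linc-128 on V (signal 117.5) and the microRNA genes cel-mir-51, cel-mir-52 and cel-mir-4936. A peak in an intron of the nuclear receptor gene nhr-17, on X from 12664981 to 12665424 (signal 138.3), lay within 200 bp of a tRNA-Tyr gene and had no summit within 100 bp in the list of replicate 3. These genes were chosen after their values were seen.

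The words with the lowest p on IV, V and X were CCTGCG (17.5% of summit and 0.325% of flank windows), GTTCGA (26.6% and 3.9%), GAACCC (20.8% and 1.95%) and CGAACC (19.5% and 1.62%), with adjusted p of 1.06e-09, 3.34e-09, 1.39e-08 and 2.03e-08 by Fisher's exact test. On I to III the 4 were also more frequent at summits, CCTGCG in 7.59% against 0.633%, GTTCGA in 16.5% against 6.33%, GAACCC in 15.2% against 4.43% and CGAACC in 16.5% against 3.80%, and none passed (Fisher's exact test, adjusted p from 0.127 to 0.296). GTTCGA, GAACCC and CGAACC match parts of the B box, the internal promoter element of tRNA genes. CCTGCG is the reverse complement of CGCAGG, which lies inside GCGCAGGG, a core sequence of sites where the dosage compensation complex loads onto X.

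GCGCAGGG was within 50 bp of 9 X summits, named by gtr-1 (806470 to 806913), ins-39 (1344846 to 1345289), T24D8.6, Y41G9A.17, mom-1 (6296351 to 6296794), R04E5.9, W02H3.3 and nspc-17 (14525850 to 14525981), and WBGene00020828 (1837652 to 1838095). Their median rank by signal among nuclear peaks was 25, against 109 for the other X peaks. The sequence was at 8 of 91 X summits in the top peaks of replicate 2, at 10 of 102 in those of replicate 3, and at 2 of 2534 X summits of the pooled list outside optimal peaks.

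X held 45.5% of nuclear optimal peaks. An X bias of the whole peak calling, equal at all signals, was argued against as the sole source. The share exceeded the 27.1% of the pooled list (one-sided binomial test, p = 1.44e-09). That 27.1% was itself above the 17.7% by length, so such a bias may be a part. Small RNA genes on X as the sole source were also argued against. X held 41.0% of the 78 peaks away from them (one-sided binomial test against length, p = 1.18e-06). These genes may still be a part, as 72 of the 106 X summits lay within 200 bp of a tRNA gene, against 31 of 127 autosomal ones. X holds 45.1% of the nuclear tRNA genes. GCGCAGGG was at 8.49% of X summits (3.96 to 15.5%), against 0.472% of their flanks and 0 of 127 autosomal summits (2-sided Fisher's exact test, p = 0.000288 and 0.000688), so dosage compensation loading sites may be one contributor, but not the whole excess, as X held 43.3% without those peaks. Leaving out both sets, X held 23 of 69 peaks (33.3%, 22.4 to 45.7%), above its length (one-sided binomial test, p = 0.00126) and not past the threshold against the pooled list (one-sided binomial test, p = 0.152), so for these few peaks an X bias of the peak calling cannot be told apart from another source. What drives this remainder stays open, and no biological explanation by NHR-179 was tested, since the design has 1 group and no control strain was analysed here.

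Small RNA genes had a nuclear optimal summit nearby more often than placement gave, at 66.5% of summits. Of GC-matched positions 1.14% lay near such a gene, and of positions within 1000 bp of a protein-coding start 0.569% did, against 0.613% by placement. The surroundings of small RNA genes take up so little sequence that neither of these tests could have come near 66.5%. No conclusion on GC content or nearness to starts is drawn from them. Reads shared between identical gene copies may contribute, as tRNA genes near a summit had 1.84 more copies than the others (12.4 ± 8.45 against 10.6 ± 8.69, SD, n = 116 and 496 genes, one-sided permutation test, p = 0.02; autosomes p = 0.0442, X p = 0.16). An earlier version of that test, which counted copies among annotated tRNA genes only, gave a difference of 1.67 (one-sided permutation test, p = 0.0308). Genes of the same sequence have the same copy number, and the 116 genes lay near 103 summits. The genes are therefore not independent, and these p may be too low. Reads shared between identical copies do not account for the whole. Of the summits, 29.6% lay near a small RNA gene whose sequence occurs once in the genome, against 0.281% placed (2-sided placement test, n = 233, p = 0.0002). Only 19 of the 116 tRNA genes near a summit occur once, so this says less about tRNA genes. Copies that differ slightly in sequence were not counted. Transcription of these genes stays open, as no expression values were analysed here.

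No summit lay within 20 kb of nhr-179 in any ce11 list. Chance spacing was argued against, as 1.39% of windows of that length on V, and 3.61% of those in its left 25%, where the gene lies, had no summit in the pooled and both replicate lists. As the locus of unc-119 was examined too, a gap by chance is uncommon but not excluded. Repeated sequence was argued against, as 6.93% of the 32-base words of the window occur elsewhere. Extra copies of the locus in the control could lower calls there, which was not tested and stays open, and no biological explanation was tested.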
